A study of Homo sapiens with 6 samples.

How the data were processed

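RNA sequencing had been done on 6 libraries of Huh7 cells, an established human liver cancer line grown in RPMI-1640 medium with fetal bovine serum. The labels divide them into 3 control libraries (a control short hairpin RNA) and 3 TRIM15 knockdown libraries (a short hairpin RNA against TRIM15). Per the labels, total RNA was enriched for mRNA and made into libraries with a directional kit, which marks the strand of each transcript. Neither the aligner, the counting step, whether strand was used in counting, nor whether replicates are separate cultures is given in the sources used here, so the spread between libraries may include little variation between cultures. How many hairpins were used and their sequences are not given either.

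The deposited table holds FPKM values (reads scaled to gene length and library size) that the authors computed, with 1 column per library, a gene length column and 58735 gene rows. The labels list genome build mm10, which is a mouse build. All 58735 row identifiers, with their start, end and strand, equal those of the human annotation GENCODE 29 on GRCh38, 58708 gene names are equal too, and 0 identifiers have the mouse form. Coordinates are therefore given on GRCh38. Each FPKM value times its gene length was a whole multiple of 1 step per library for 100% of values (tolerance 0.01), which gave back whole reads per gene. The library size implied by this step differed from the sum of reads by -0.370 to -0.359% in the control libraries and by 1.04 to 1.27% in the knockdown libraries, so the FPKM values carry a scaling factor per library. Reads per library counted back this way were 17715210 to 18217903 for control and 17332508 to 19556855 for knockdown. Intervals on read counts are exact Poisson 95% intervals and cover counting error only.

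Values were put on the log2(FPKM + 1) scale, which understates the fold change of genes near 1 FPKM. Of the 58735 gene rows, 32030 were above 0 in at least 1 library, and the 14847 with at least 0.5 FPKM in 3 or more of the 6 libraries were tested. Of these, 11652 were protein-coding. The comparison of knockdown with control used limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p under 0.05. Adjusted p values of genes come from this model unless another is named. Standard errors (SE) of log2 fold changes come from the same model, and SD is the spread of the 3 libraries of a group. TRIM15 was also compared by a two-sided exact permutation test of the group means, for which 3 against 3 libraries allow no p below 0.1.

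Gene groups were 45 lists with 904 entries (852 distinct genes), written before the data were examined. Of the listed genes, 21 were found by an older symbol. The 42 lists with at least 5 tested genes were tested together with camera from limma at its preset correlation between genes of 0.01, two-sided and adjusted over the lists. Camera with a correlation estimated for each list, and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. A planned enrichment of GO or KEGG terms was not done because the table holds no such terms. Its column of transcription factor families was tested instead with camera, for the 14 families with at least 10 tested genes, after the table had been seen.

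Named genes were taken by a rule written at the same time. They were the genes of the study's axis, the 6 largest rises and 6 largest falls past the threshold without overlap between groups, and up to 4 genes from each list that was called or had 3 or more members past the threshold. Because the largest changes included short RNAs with few reads, a second set was added after the values were seen, namely the 8 largest rises and 8 largest falls among protein-coding genes with at least 100 reads on average. Not every gene taken by these rules is described. Other genes are named as exceptions, with a statement that they were chosen after their values were seen, or as the most abundant markers of other cell types.

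The procedure was tested on simulated data with 14968 genes, in 5 runs with 200 changed genes each. It recovered 21.2% of genes changed 1.2-fold, 56.1% of those changed 1.5-fold and 72.4% of those changed 2-fold. False calls averaged 11.2 per run, or 10.1% of the calls, which is above the 5% that the threshold aims at. A moved list was called in 5 of 5 runs and 0 other lists were called. Genes were drawn independently, so these runs do not check the list test where genes are correlated. With 200 changed genes the p cutoff is stricter than with 2824 calls, so the shares recovered do not carry over to the real data.

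A scan of 3' UTR words was added. For each 7-base word present in at least 100 genes (15732 words), the log2 fold change of 11448 genes was regressed on presence of the word in the annotated 3' UTR of at least 50 bases, with 3' UTR length and GC content as terms. The largest z values were set against 100 permutations of the residuals over genes. Coding sequences of the same genes were scanned in the same way (16279 words). In simulated data, a planted word was found in 5 of 5 runs. GC content was taken from the annotated transcripts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 ran the word counts and drew the figures.

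Alternatives fixed in advance were other pseudocounts (0.1 and 0.5), no filter or a floor of 1 FPKM, median-of-ratios and quantile scaling, no variance trend, replicate number as a block, a minimum log2 fold change of 1, the other set tests, and leaving out each library in turn. Alternatives chosen after seeing the data were limma voom on the whole reads, removal of a smooth trend on GC content and gene length, and leaving out genes with matches to the words found. The closing section gives their effect.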

Results

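Transcript levels were measured by RNA sequencing in Huh7 liver cancer cells with a control hairpin (3 libraries) or a hairpin against TRIM15 (3 libraries). Depth was 18143502, 17715210 and 18217903 reads in control replicates 1 to 3, and 18664890, 19556855 and 17332508 reads in knockdown replicates 1 to 3. Between replicates, the squared difference per gene was 1.89 to 2.70 times sampling noise, with 1 expected from sampling alone. Pearson's r across genes on the log2 scale was 0.991 to 0.992 within groups and 0.988 to 0.989 between them (genes are not independent replicates). The first principal component held 34.3% of the variance and separated the groups. Mitochondrial reads made up 4.07% ± 0.0257 of reads in control and 3.80% ± 0.0495 in knockdown libraries (SD, n = 3).

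The comparison asks how transcript levels change when TRIM15, an E3 ubiquitin ligase of the tripartite motif family, is reduced. TRIM15 (ENSG00000204610, chromosome 6, 30163206 to 30172696 on GRCh38) fell from 5.05 ± 0.147 to 2.62 ± 0.563 FPKM (SD, n = 3), which is 51.8% of control. The log2 fold change was -0.75 (SE 0.106, adjusted p = 0.00416). The exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Reads were 235, 226 and 223 in the control libraries and 153, 105 and 111 in the knockdown libraries; the highest knockdown count has a 95% interval of 130 to 179, below the lowest control interval, which starts at 195.

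By its title, the series concerns TRIM15 together with AKT, FOXO1 and LASP1 and the response to tyrosine kinase inhibitors. LASP1, FOXO1, AKT1 and AKT2 did not pass the threshold. LASP1 (chromosome 17, 38869859 to 38921770), an actin-binding adaptor, was at 48.7 ± 1.55 FPKM in control and 48.1 ± 0.566 in knockdown (SD, n = 3; adjusted p = 0.742). FOXO1 (chromosome 13, 40469953 to 40666597), a transcription factor inhibited by AKT, was at 2.12 ± 0.0633 and 1.88 ± 0.257 FPKM (adjusted p = 0.34). AKT1 (chromosome 14) was at 6.72 ± 0.130 and 7.53 ± 0.542 FPKM (adjusted p = 0.101), and AKT2 (chromosome 19) at 10.7 ± 0.470 and 11.5 ± 0.299 FPKM (adjusted p = 0.13). With limma voom on whole reads, AKT1 (log2 fold change 0.16, adjusted p = 0.00385) and AKT2 (0.11, adjusted p = 0.00847) were past the threshold. Protein amount and phosphorylation were not measured.

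**Figure D1:**
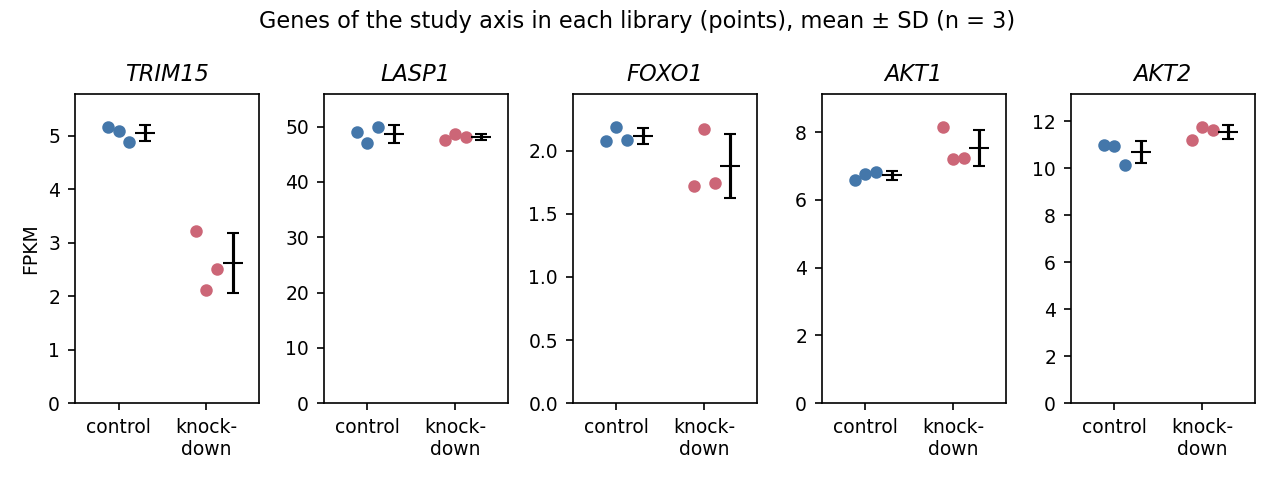
FPKM of TRIM15, LASP1, FOXO1, AKT1 and AKT2 in each library (points), with group means and SD (n = 3 per group). TRIM15 fell to 51.8% of control, while the other genes did not pass the threshold.

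Many transcripts moved by small amounts, in both directions. Of 14847 genes tested, 2824 (19.02%) differed, with 1326 higher and 1498 lower in the knockdown. Higher genes were 47.0% of these (95% exact binomial interval 45.1 to 48.8, which treats genes as independent). The median absolute log2 fold change of the called genes was 0.22, 95 of them changed at least 1.5-fold (30 higher, 65 lower), and 9 reached a log2 fold change of 1. The groups did not overlap in 5613 genes (37.8%), where chance gives 10% for 3 against 3. The count fell to 1869, 1871 and 1770 without knockdown replicate 1, 2 and 3.

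Among well-covered protein-coding genes, the largest fall was in CCNC (chromosome 6, 99542380 to 99568973), which encodes cyclin C of the Mediator kinase module. It went from 22.7 ± 0.631 to 9.36 ± 0.450 FPKM (SD, n = 3; log2 fold change -1.19, SE 0.0403, adjusted p = 5.34e-05). UHMK1 (chromosome 1), a serine/threonine kinase, fell from 11.02 ± 0.474 to 5.27 ± 0.235 FPKM (-0.94). Further falls were in COMMD8 (-0.85), the deubiquitinase USP46 (-0.80), the mitotic kinase NEK7 (-0.80), the phosphatase PTP4A2 (31.2 ± 0.864 to 17.8 ± 0.279 FPKM, -0.78) and the actin-severing factor CFL2 (-0.75). OGFR (chromosome 20, 62804835 to 62814000), a receptor for opioid growth factor, rose from 8.54 ± 0.353 to 17.2 ± 0.812 FPKM (log2 fold change 0.93, SE 0.0449, adjusted p = 0.000128). HABP4, which overlaps CDC14B on the opposite strand, rose by 0.90 on the log2 scale. The nucleolar protein gene NOLC1 rose from 29.2 ± 0.346 to 51.5 ± 0.505 FPKM (0.80), and the tropomyosin gene TPM4 from 87.1 ± 0.665 to 150 ± 0.379 FPKM (0.78, adjusted p = 8.24e-06). STX12 (0.81), TMEM216 (0.79) and TUFT1 (0.73) also rose. These log2 fold changes are on the log2(FPKM + 1) scale, and each of these calls held under the other pseudocounts, filters, scalings and variance model, with replicate number as a block, with voom, after the GC and length correction and without any 1 library. With a minimum log2 fold change of 1, only CCNC among them would be called.

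The rule for large changes also took 7 short or pseudogene transcripts, all of them uncertain. MT-TL2 (-1.12) and MT-TD (-1.11), which encode mitochondrial tRNAs, MIR331 (-1.09) and the pseudogene TCEA1P2 (-1.03), which lies inside GOLGA4, were lower. MIR3939 (1.14) and SNORA47 (0.89), which lie inside Z94721.1 and ZBED3, were higher. MIR4633, inside ISOC1, was listed at 0 in all control libraries and had 2, 1 and 4 reads in the knockdown libraries. Mean reads for the 7 were 1.17 to 85.5. With voom on whole reads the adjusted p values of MIR4633, MIR3939, SNORA47, MT-TD and MIR331 were 0.0553, 0.0883, 0.122, 0.142 and 0.1, and without a filter on low values those of MT-TL2 and TCEA1P2 were 0.0869 and 0.13. Leaving out 1 library ended each of these calls except that of MT-TD, with the highest adjusted p for MIR4633 without control replicate 2 (0.0624), MIR3939 without knockdown replicate 3 (0.0747), SNORA47 without knockdown replicate 2 (0.0738), MT-TL2 without control replicate 2 (0.0685), MIR331 without control replicate 2 (0.116) and TCEA1P2 without knockdown replicate 3 (0.119).

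**Figure D2:**
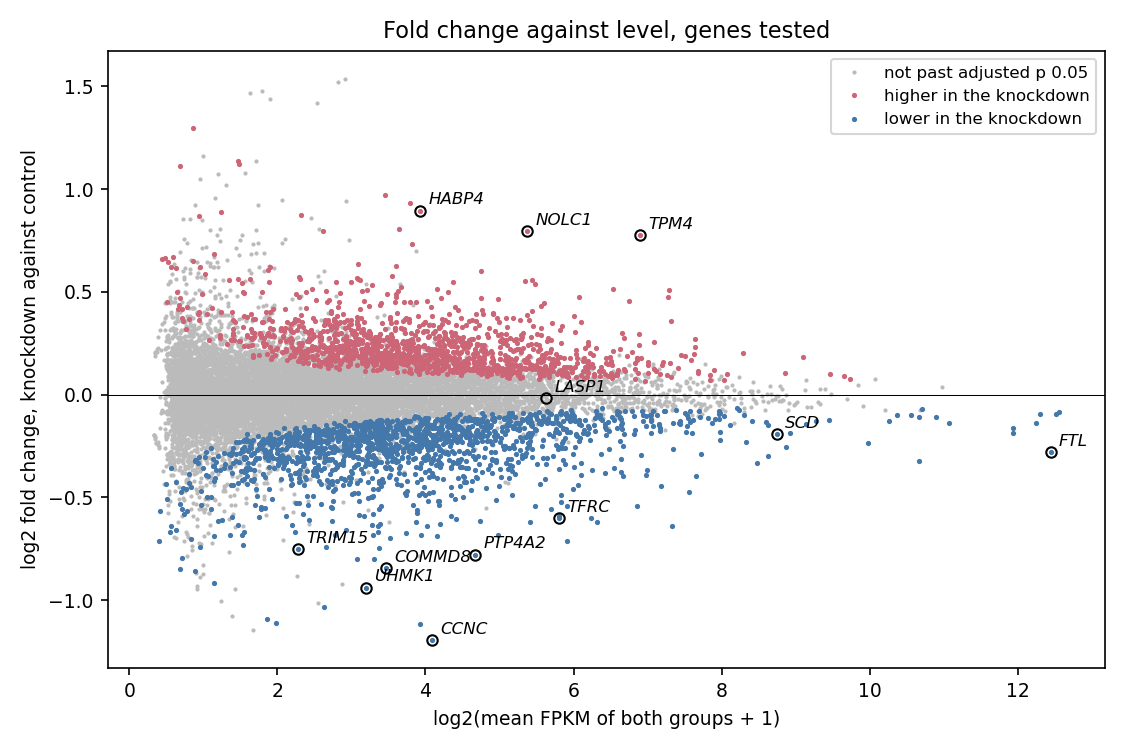
Log2 fold change (knockdown minus control) of 14847 genes against log2 of the mean FPKM plus 1, with genes past adjusted p 0.05 coloured and selected genes named. The 1326 higher and 1498 lower genes lie mostly within 1 log2 unit of 0.

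Genes of the AKT and kinase-inhibitor pathways moved in both directions, without a shift of any list as a whole. Of 25 tested FOXO targets, 4 were higher and 3 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.944), among them the apoptosis gene BBC3 (log2 fold change 0.46, SE 0.0887), the thioredoxin inhibitor TXNIP (0.38, SE 0.0556) and the superoxide dismutase SOD2 (-0.25, SE 0.0354). PI3K-AKT-mTOR components had 2 higher and 4 lower of 31 (4 and 6 adjusted over the list alone; adjusted p = 0.913), with MLST8, an mTOR complex subunit, at 0.27. Among 22 kinase-inhibitor targets and ligands, 3 were higher and 5 lower (3 and 5 adjusted over the list alone; adjusted p = 0.6). The receptor gene FGFR3 rose from 59.3 ± 0.712 to 76.1 ± 0.814 FPKM (SD, n = 3), while MET (-0.23) and ERBB3 (-0.23), also receptor genes, fell. MAPK feedback genes had 4 higher and 2 lower of 15 (5 and 2 adjusted over the list alone; adjusted p = 0.435). CCND1, the cyclin D1 gene, fell from 60.9 ± 1.54 to 41.1 ± 0.558 FPKM (-0.56), and the phosphatase gene DUSP5 rose (0.34). Drug efflux genes had 0 higher and 1 lower of 8 by limma (the same adjusted over the list alone; adjusted p = 0.913). Among members without a match to a lower 3' UTR word (described below), 0 of 5 FOXO targets and 0 of 7 PI3K-AKT-mTOR components were lower. The same held for 0 of 7 MAPK feedback genes, but 2 of 11 kinase-inhibitor targets and ligands were lower. Genes without a match in the 3' UTR are seldom lower in general (3.92% of 5000 such genes outside the mitosis list).

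Mitosis genes fell together. Of 26 tested, 16 were lower and 1 was higher (17 and 2 adjusted over the list alone), with a median log2 fold change of -0.16 and a camera adjusted p = 1.95e-05. The list gave adjusted p = 0.495 with an estimated correlation. CCNA2, which encodes cyclin A2, fell from 76.7 ± 1.75 to 58.1 ± 0.776 FPKM (SD, n = 3; -0.39), and the cyclin-dependent kinase gene CDK1 from 52.2 ± 1.38 to 42.0 ± 2.15 FPKM (-0.31). The mitotic motor genes KIF11 (-0.31, SE 0.0254) and CENPE (-0.31, SE 0.0338) fell as well. BIRC5, the survivin gene, was the 1 member that rose (0.24), and was chosen after its value was seen. A 7- or 8-base form of the 3' UTR words tied to lower values was present in 6 of the 26 genes, among them CCNA2, CDK1, KIF11 and CENPE. Of 27 DNA replication genes, 6 were lower and 1 was higher (8 and 1 adjusted over the list alone; adjusted p = 0.258), with TYMS at -0.38, MCM3 at -0.37 and the cyclin E1 gene CCNE1 at 0.36. Replication-dependent histones had 0 members past the threshold of 10 by limma (0 adjusted over the list alone; adjusted p = 0.638). BCL2 family genes had 3 higher and 2 lower of 13 (3 and 4 adjusted over the list alone; adjusted p = 0.871); the survival gene MCL1 fell (-0.36) and the death effector BAX rose (0.28). p53 targets had 5 higher and 1 lower of 17 (6 and 4 adjusted over the list alone; adjusted p = 0.6), with BTG2 at 0.34.

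Target genes of ATF4, the factor of the amino acid response, rose together. Of 21 tested, 12 were higher and 0 lower by limma (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.11 and a camera adjusted p = 7.01e-05. The list gave adjusted p = 0.314 with an estimated correlation. DDIT4, an inhibitor of mTORC1 signalling, rose from 2.99 ± 0.502 to 4.86 ± 0.409 FPKM (SD, n = 3; 0.56), DDIT3 from 9.43 ± 0.670 to 14.0 ± 1.26 FPKM (0.52), and SESN2 from 11.3 ± 0.735 to 15.9 ± 0.484 FPKM (0.45). DDIT3 overlaps MARS (48.9 FPKM on average) and MBD6 on the opposite strand, so its values may include their reads if strand was not used in counting. Immediate early genes, which respond fast to growth signals and stress, had 8 higher and 1 lower of 15 (8 and 2 adjusted over the list alone), a median of 0.27 and an adjusted p = 0.0032. They gave adjusted p = 0.495 with an estimated correlation. EGR1 rose from 1.33 ± 0.216 to 2.41 ± 0.369 FPKM (0.54), ATF3 by 0.45 and IER2 by 0.38 on the log2 scale. JUNB, the 1 member that fell (-0.20), was chosen after its value was seen. Unfolded protein response genes had 2 higher and 6 lower of 20 (2 and 7 adjusted over the list alone; adjusted p = 0.258). The chaperone genes CANX (228 ± 6.81 to 173 ± 0.595 FPKM, -0.40), DNAJB11 (-0.38) and PDIA3 (-0.37) of the endoplasmic reticulum fell. Heat shock genes had 2 higher and 2 lower of 13 (the same adjusted over the list alone; adjusted p = 0.871), with HSPA8 at -0.30 and DNAJB1 at 0.20. NRF2 and ferroptosis genes had 4 higher and 3 lower of 22 (5 and 3 adjusted over the list alone; adjusted p = 0.597), and the transferrin receptor gene TFRC fell from 66.4 ± 2.12 to 43.4 ± 0.629 FPKM (-0.60).

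**Figure D3:**
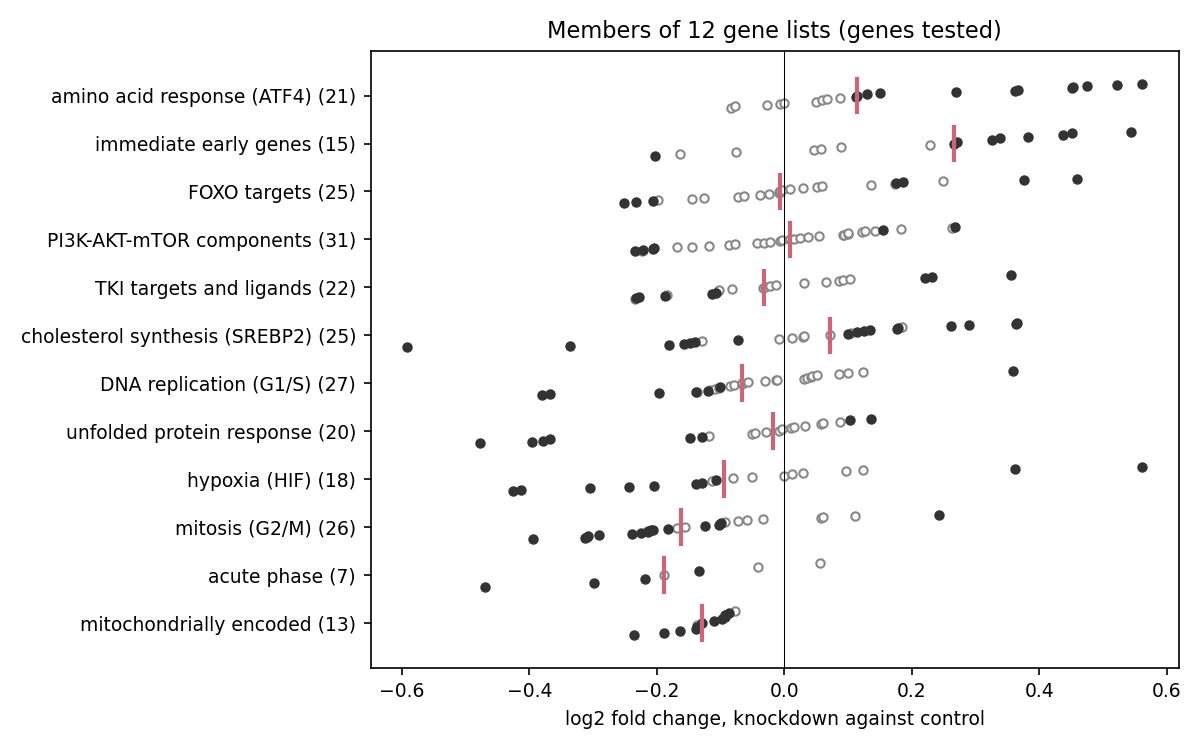
Log2 fold change of each tested member (points, filled if past adjusted p 0.05; numbers tested in parentheses) of the 5 called lists and of 7 others, with the median of each list as a bar. Median values were -0.16 for mitosis genes, 0.11 for ATF4 targets and 0.27 for immediate early genes.

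Acute phase genes, which liver cells secrete in inflammation, fell weakly. Of 7 tested, 4 were lower and 0 higher by limma (the same adjusted over the list alone), with a median of -0.19 and a camera adjusted p = 0.0419. The list gave adjusted p = 0.599 with an estimated correlation. The fibrinogen genes FGG (57.3 ± 1.09 to 46.4 ± 1.49 FPKM, SD, n = 3; -0.30) and FGB (271 ± 7.37 to 233 ± 6.01 FPKM, -0.22) fell. The list was no longer called without control replicate 1, 2 or 3 (adjusted p = 0.0522, 0.0585 and 0.0587) or without knockdown replicate 2 or 3 (0.065 and 0.0985). With 1 library left out the median ranged from -0.24 (control replicate 1) to -0.12 (control replicate 3). With no filter, which adds members with low values, it was -0.0156. Hepatocyte secreted proteins had 1 higher and 6 lower of 23 (the same adjusted over the list alone; adjusted p = 0.871). Hepatocyte transcription factors had 1 higher and 6 lower of 16 (2 and 6 adjusted over the list alone; adjusted p = 0.597), and CEBPA fell from 71.4 ± 3.94 to 55.6 ± 0.700 FPKM (-0.35). Bile acid and drug metabolism genes had 0 past the threshold of 7 by limma (0 adjusted over the list alone; adjusted p = 0.867). Fetal liver and stem cell markers had 1 higher and 3 lower of 14 (4 and 4 adjusted over the list alone; adjusted p = 0.649), with the let-7 inhibitor LIN28B at -0.31.

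Metabolic lists were mixed. Cholesterol synthesis genes had 10 higher and 7 lower of 25 (11 and 8 adjusted over the list alone; adjusted p = 0.435): the mevalonate pathway gene MVD rose from 33.1 ± 0.672 to 42.8 ± 1.23 FPKM (SD, n = 3; 0.36), while the sterol oxidase gene MSMO1 fell from 66.0 ± 3.53 to 43.5 ± 1.05 FPKM (-0.59). The 11 members without a match to a lower 3' UTR word (described below) had 6 higher and 0 lower by limma, with a median log2 fold change of 0.13. The words were chosen on these fold changes, so genes without a match lean higher in general. Of 3032 genes with none in 3' UTR or coding sequence, 18.0% were higher and 2.84% lower. The 11 members may still hold a match in coding sequence, so this background is stricter than their own selection. Fatty acid synthesis genes had 6 higher and 3 lower of 16 (the same adjusted over the list alone; adjusted p = 0.597), with ACLY at -0.25 and SCD at -0.19. Fatty acid oxidation genes had 1 higher and 1 lower of 17 (2 and 2 adjusted over the list alone; adjusted p = 0.677). Gluconeogenesis and amino acid catabolism genes had 2 higher and 0 lower of 8 by limma (the same adjusted over the list alone; adjusted p = 0.435). Glycolysis genes had 2 higher and 3 lower of 19 (the same adjusted over the list alone; adjusted p = 0.796); the glucose transporter gene SLC2A1 rose from 2.93 ± 0.394 to 4.84 ± 0.226 FPKM (0.57), PFKL rose (0.32) and LDHA fell (-0.18). Hypoxia genes had 2 higher and 8 lower of 18 (3 and 8 adjusted over the list alone; adjusted p = 0.258), with BNIP3L at -0.41.

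Transcripts of the mitochondrial genome fell by a small amount. Of 13 tested, 11 were lower and 0 higher by limma (12 and 0 adjusted over the list alone), with a median of -0.13 and a camera adjusted p = 5.55e-05. The list gave adjusted p = 0.599 with an estimated correlation. MT-ND1 fell from 1088 ± 18.8 to 923 ± 6.06 FPKM (SD, n = 3; -0.24). The number of lower members was 1 with no filter, 1 under quantile scaling, 5 without a variance trend and 7 without control replicate 2 or knockdown replicate 2. The median stayed at -0.13 with no filter and without a variance trend, and was 0 under quantile scaling. After the GC and length correction it was -0.08, with 9 members lower. Under quantile scaling the list was no longer called (adjusted p = 0.901), and MT-ND4 went from -0.16 to 0.0145. Nuclear oxidative phosphorylation genes had 2 higher and 4 lower of 25 (the same adjusted over the list alone; adjusted p = 0.638), with the cytochrome c gene CYCS at -0.29. Ribosomal protein genes had 1 higher and 3 lower of 30 (0 and 0 adjusted over the list alone; adjusted p = 0.6). Reference genes had 1 higher and 6 lower of 14 (3 and 8 adjusted over the list alone; adjusted p = 0.258), with YWHAZ at -0.16. Mitochondrial and ribosomal protein genes have many copies in the nuclear genome, and how reads shared between copies were counted is not given in the sources used here.

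Most markers of fibroblasts, endothelium and immune cells were too low to test. Below 0.5 FPKM in all libraries were 8 of 12 fibroblast and stellate cell markers, 11 of 12 endothelial markers and 10 of 13 immune markers. The highest fibroblast marker, LUM, was at 57.6 ± 1.95 FPKM in control and 50.7 ± 1.25 in knockdown (SD, n = 3; log2 fold change -0.18, adjusted p = 0.00931), the highest endothelial marker, ESAM, at 0.546 ± 0.139 and 0.550 ± 0.237, and the highest immune marker, CD14, at 14.0 ± 0.585 and 13.7 ± 0.383. Of the tested members, 2 of 4 fibroblast markers were lower, while 0 of 1 endothelial and 0 of 3 immune markers passed the threshold by limma (the same counts adjusted over each list alone). Bile duct markers had 2 higher and 0 lower of 8 by limma (2 and 1 adjusted over the list alone; adjusted p = 0.871). SOX9 rose (0.22, adjusted p = 0.000745; chosen after its value was seen), and KRT19 was at 175 ± 0.479 and 172 ± 2.42 FPKM.

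Lower and higher genes differed in short words of their 3' UTR sequence. Over 11448 genes, the word most strongly tied to lower values was ATGAATA (z = -23.4, against -4.69 for the most extreme of 100 permutations), and that most tied to higher values was TCGGAGA (z = 9.29, against 4.72). A further lower word, GGAAATA, had z = -10.3. In coding sequence the most extreme words were again ATGAATA (z = -8.07, most extreme permuted -4.78) and TCGGAGA (z = 10.4, most extreme permuted 4.92). They were not alone there, with 12 coding words below the permuted range and 42 above it. Those above included AACCCTA (z = 7.53) and TTCACAC (z = 6.70), which do not overlap TCGGAGA. C2H2 zinc finger genes, which leaned higher as a family (described below), were not left out. The coding scan therefore cannot separate a word from that family. When the 3' UTR word was picked on 5724 genes, the pick for lower genes (TGAATAA, which overlaps ATGAATA) ranked 2 of 13781 words in the 5724 other genes (z = -14.6), and the pick for higher genes (GGAGAAA) ranked 2 as well (z = 7.06). GGAGAAA shares GGAGAA with TCGGAGAA but is not among its forms counted below, so this split did not check TCGGAGA itself. Over all 11448 genes GGAGAAA had z = 9.20 in 2502 genes, against 9.29 for TCGGAGA in 223 genes. The median log2 fold change was -0.12 (bootstrap SE 0.00769) in 778 genes with the 8-base form ATGAATAA, -0.06 (SE 0.00339) in 2340 genes with a 7-base form, -0.02 (SE 0.00317) in 1436 genes with a 6-base form and 0.04 (SE 0.00192) in 6894 genes with none. Of the 64 genes with TCGGAGAA, 42.2% were higher, against 9.86% of the 10487 genes with no form of it. Of the searched lower genes, 1052 of 1387 (75.9%) held a 7- or 8-base form of the lower words, against 3656 of 8936 genes not past the threshold (40.9%). The words were chosen on these fold changes, so the shares are descriptive. Among falls of at least 1.5-fold, 36 of 39 searched genes held such a form (43.0% of all searched genes did). The falls of CCNC, UHMK1, COMMD8, USP46, NEK7, PTP4A2, CFL2, CCND1, MCL1, TFRC, MSMO1, CANX, PDIA3, DNAJB11 and BNIP3L were all in genes with a 7- or 8-base form of a lower word in the 3' UTR. Other falls were not: TYMS, FGG, FGB and TRIM15 held no form there, and JUNB, CXCL2 and VIM held a 6-base form alone. Among the rises, TPM4 and TUFT1 held TCGGAGAA and HABP4, NOLC1 and TMEM216 a 7-base form of it, whereas OGFR and STX12 held none in the 3' UTR. Coding matches of these single genes are not given here, so genes without a 3' UTR form may still hold a word in coding sequence. A lower word did not always go with a fall: TPM4, OGFR, SLC2A1 and DDIT4 rose and held a 7-base form of at least 1 lower word in the 3' UTR.

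**Figure D4:**
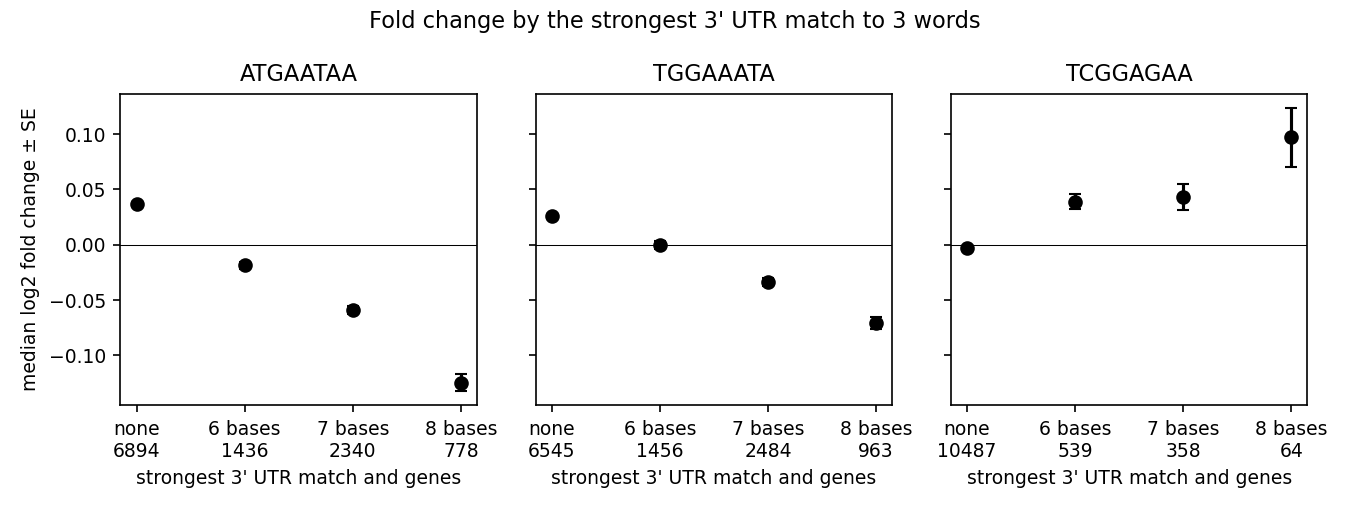
Median log2 fold change (knockdown minus control) by the strongest form of each word in the 3' UTR, with bootstrap SE as bars. For ATGAATAA it goes from 0.04 in 6894 genes with no form to -0.12 in 778 genes with the 8-base form.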

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

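Alternatives chosen only after the results were seen were voom on whole reads, removal of a trend on GC content and gene length, and leaving out genes with matches to the 3' UTR words. Further tests chosen after results were seen are named under the other observations. All other alternatives, the lists and the rule for the main named genes were set before the data were examined. The count of 2824 genes stayed within 1.5 times under the other pseudocounts, filters, scalings, variance model, voom and the GC and length correction; voom called 4058 genes, 2692 of them shared, and the correction 2444, with 2023 shared. Without 1 library it ranged from 1770 to 2339, and the share of higher genes from 44.4 to 47.7%, with fewer libraries in each fit. With replicate number as a block the count was 1913 (1804 shared), although same-number deviations of control and knockdown correlated at only 0.0125, 0.00862 and 0.0133 across genes, so the numbers give no sign of pairing. A minimum log2 fold change of 1 left 9 genes (44.4% higher), and the share was 45.0% without a variance trend, the cause of which was not tested. Among 2049 searched genes without a match to any word, 296 differed when p values were adjusted over these genes alone (234 higher, 62 lower), and 263 were higher and 72 lower when adjusted over all genes tested. The real grouping gave 2824 genes and the highest other split of the 6 libraries gave 1; the real grouping was the 1 of 10 splits with as many, and 10 splits cannot give a share under 0.05. TRIM15 differed by -0.94 as log2(FPKM + 0.1), in the same direction.

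Of the 42 lists, 5 were called, 3 under quantile scaling, 21 by fry (7 higher, 14 lower), which compares no list with other genes, and 4 to 5 without 1 library. Camera with an estimated correlation called 0 lists, with 3 at an unadjusted p under 0.05. Its adjusted p was 0.495 for mitosis and for immediate early genes, 0.314 for ATF4 targets and 0.599 for acute phase and for mitochondrially encoded genes. The estimated correlation was 0.0902, 0.0294, 0.252 and 0.332 for mitosis, immediate early, acute phase and mitochondrially encoded genes, above the preset 0.01. For ATF4 targets it was -0.0035, below the preset, yet the unadjusted camera p rose from 5.01e-06 to 0.00748. A higher correlation between genes therefore does not account for the loss of that call. Something else in this form of camera weakened that list and may have weakened the others too. The 0 calls can therefore not be read as an effect of correlation between genes alone. Which other part of the test caused this was not examined. Some alternatives called further lists: voom added the unfolded protein response (adjusted p = 0.0106) and reference genes (0.00939), the GC and length correction DNA replication and MHC class I presentation (0.03 each), no filter MHC class I presentation (0.0288), and leaving out genes with a 3' UTR match cholesterol synthesis (0.0106) and autophagy and lysosome (0.0444). Over 19 alternatives, adjusted p ranged from 2.45e-09 to 0.495 for mitosis (18 past 0.05), 1.63e-08 to 0.314 for ATF4 targets (18), 3.78e-05 to 0.495 for immediate early genes (18), 1.54e-17 to 0.901 for mitochondrially encoded genes (17) and 0.00496 to 0.599 for acute phase genes (10). The acute phase list missed the threshold with no filter (0.243), the stricter filter (0.0599) and quantile scaling (0.0764), and without 1 library its adjusted p was 0.0172 to 0.0985. Quantile scaling, which forces equal distributions and so acts most on the most abundant transcripts, gave 0.901 for mitochondrially encoded genes. Of 155 named genes tested, 109 kept their side of the threshold and direction in each alternative fitted per gene and 46 did not in at least 1. MT-ND4 turned to 0.0145 under quantile scaling, LASP1 (-0.0413 to 0.00295 without 1 library) turned without control replicate 3, and RPL5 turned to 0.0111 after the GC and length correction; the cause was not tested. Simulated data with 200 changed genes per run gave back 21.2% of genes changed 1.2-fold, a share that does not carry over to the real data. Small changes can still be missed.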

Other observations

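The tests of transcription factor families, of the word TCGGAGA and the shares of list members past the threshold set beside other genes were chosen only after results were seen, and the order of site forms was predicted when the 7-base values were already known. Autophagy and lysosome genes had 8 higher and 4 lower of 22 tested (the same adjusted over the list alone; camera adjusted p = 0.6), with rises in the kinase gene ULK1 (0.30) and in BECN1 (0.25) on the log2 scale. Of 26 genes of the TRIM family, 4 were lower and 1 was higher (the same adjusted over the list alone; adjusted p = 0.567); the falls were in TRIM37 (11.5 ± 0.637 to 7.59 ± 0.276 FPKM, SD, n = 3), TRIM14 (5.92 ± 0.142 to 4.13 ± 0.236 FPKM), TRIM44 (-0.30) and TRIM24 (-0.26). BECN1 and TRIM14 overlap the more abundant genes PSME3 and NANS on the opposite strand. YAP/TEAD targets had 5 higher and 4 lower of 14 (6 and 5 adjusted over the list alone; adjusted p = 0.6): the matricellular genes CYR61 (75.3 ± 3.24 to 108 ± 2.16 FPKM) and CTGF (90.0 ± 1.93 to 124 ± 2.27 FPKM) rose, while FSTL1 (-0.49) and DLC1 (-0.45) fell. Focal adhesion and actin genes had 3 higher and 6 lower of 29 (4 and 6 adjusted over the list alone; adjusted p = 0.871), with the integrin gene ITGAV at -0.25 and ENAH at -0.23. EMT and matrix genes had 0 higher and 3 lower of 19 by limma (the same adjusted over the list alone; adjusted p = 0.6), with the vimentin gene VIM at -0.17. Among members without a match to a lower 3' UTR word, 0 of 7 TRIM family, 0 of 15 focal adhesion, 0 of 4 EMT and 0 of 1 YAP/TEAD genes were lower. Of such autophagy and lysosome members, 1 of 10 was lower.

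TGF-beta targets had 2 higher and 2 lower of 14 (the same adjusted over the list alone; adjusted p = 0.979), with ID3 at 0.26 and SMAD6 at -0.35. WNT targets had 3 higher and 1 lower of 11 (the same adjusted over the list alone; adjusted p = 0.731), with MYC at 0.27. NF-kB and cytokine genes had 3 higher and 3 lower of 18 (4 and 3 adjusted over the list alone; adjusted p = 0.944), with the chemokine genes CXCL1 at 0.36 and CXCL2 at -0.30. Interferon-stimulated genes had 1 higher and 2 lower of 17 (the same adjusted over the list alone; adjusted p = 0.6), and MHC class I presentation genes 0 higher and 3 lower of 10 by limma (the same adjusted over the list alone; adjusted p = 0.243). Among 14 transcription factor families, C2H2 zinc fingers had 42 higher and 15 lower of 443 (camera adjusted p = 0.0072, and adjusted p = 0.135 with an estimated correlation), and bZIP factors 10 higher and 3 lower of 43 (adjusted p = 0.0072, and adjusted p = 0.135 with an estimated correlation). Of the zinc finger genes with a match to the higher word, 25 of 199 (12.6%) were higher, against 16 of 236 (6.78%) without; this difference was not tested. Median and mean log2 fold change differed in sign for FOXO targets, the BCL2 family, glycolysis, heat shock, TGF-beta targets and autophagy and lysosome genes, lists that were not called.

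A candidate explanation for many of the lower genes is that the knockdown hairpins act on other transcripts through short seed matches, as microRNAs do. The most extreme lower word in 3' UTRs had z = -23.4 (most extreme permuted -4.69), genes with the 8-base form lay -0.16 (SE 0.00793) from genes with none, and 86 of 3032 searched genes without a match to the lower words were lower, under the bound of 100 set in advance, but 545 of them were higher (median 0.06), and such an upward shift also lowers that count. Against GC content and gene length as the whole cause of the falls, 1325 genes were lower after that trend was removed and 1498 before. The trend may still add to them, as fold changes rose with GC content (rank correlation 0.313, medians -0.07 and 0.06 in the 20% of genes with the lowest and the highest GC content) and 2023 of 2824 calls were shared after removal. The correlation was weaker, at 0.147, among 2049 searched genes without a match to any word. The coding sequence of TRIM15 itself holds ATGAATA (chromosome 6, 30168430 to 30168436, exon 3) and TGGAAATA (30170994 to 30171001, exon 6 or 7 by transcript), found together in 0.662% of 2718 genes of similar coding length, or in 2.28% with TGGAAAT in place of the longer word. TRIM15 was searched for every 7- and 8-base form, and the forms counted in other genes were chosen from what it held. Both shares therefore understate how often some pair of forms occurs by chance. Since the hairpin sequences are not known here, loss of TRIM15 remains untested as a cause of any single fall, and a hairpin with another seed or a rescue would be needed to separate them.

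For part of the higher genes, a candidate explanation is a seed effect of the control hairpin, whose targets would be lower in control cells. The most extreme higher word, TCGGAGA, had z = 9.29 (most extreme permuted 4.72), with GGAGAAA, which is not a form of it, close behind (z = 9.20). Of 4019 searched genes with a match to the higher word, 695 (17.3%) were higher, against 559 of 7558 (7.40%) without one. Those 559 were among 1254 searched higher genes, so matches to forms of TCGGAGAA do not account for the higher genes as a whole. Genes with GGAGAAA alone were not counted as matches, so a seed that pairs with it was not covered. TCGGAGA was chosen on these fold changes, so the shares are descriptive. The guide start that would pair with the 8-base form TCGGAGAA, TTCTCCGA, is as background also the start of a widely used non-targeting sequence. Whether that sequence was used here, and which of its strands would act as the guide, is not given in the sources used here. Matches to forms of TCGGAGAA alone do not account for the rise of ATF4 targets. The 13 members without such a match had a median log2 fold change of 0.11 (bootstrap SE 0.0747). Of these, 7 were higher, against 7.32% of other genes without a match. Whether the 13 members hold GGAGAAA was not examined, so a seed effect of the control hairpin through that word stays open. The GC content and length trend does not account for the rise of ATF4 targets either. After its removal the median was 0.10 (SE 0.0672, camera adjusted p = 0.000243) and 11 of 21 were higher, against 9.03% of other genes. A response to lower TRIM15 stays open for these genes, as does an indirect effect of either hairpin.

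The fall of mitosis genes is not accounted for by matches in 3' UTRs alone. The 17 members without such a match had a median log2 fold change of -0.10 (bootstrap SE 0.0298), where the whole list had -0.16, and 9 of the 17 were lower, against 3.92% of other genes without one. Matches in coding sequence stay open, since just 4 members had a match in neither part (median 0.0137, SE 0.0836, 1 higher and 1 lower), too few to decide. After removal of the GC content and length trend the median was -0.13 (adjusted p = 6.47e-05). Slower cycling after TRIM15 loss may underlie it, as may a difference in cell density or an indirect effect of falls elsewhere, and none of these was tested.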
